A study of Mus musculus with 6 samples.

How the data were processed

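Bulk RNA sequencing of cultured mouse neural stem cells was analysed in 6 libraries, 3 untreated (Control) and 3 given Wnt3a plus R-spondin 1 (WR). Groups and replicate numbers were taken from the sample titles. The series title carries a single-cell tag, but per the labels the libraries were made from total RNA with an Illumina TruSeq kit, and the tables hold 1 value per gene and library, so the data were treated as bulk. Per the submitters' processing notes, Bowtie 0.12.2 was among the tools and mm8 and mm9 among the genome builds named, with no role given for either. The counting program, the annotation, the handling of strand and of reads that map to several places are not given in the sources used here. The tables hold no coordinates and the build behind them is not settled, so no genomic positions are printed. Whether reads of near-identical gene copies, of overlapping genes and of antisense partners were told apart in these counts is therefore not known.

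The deposited read counts are whole numbers per gene and library, per the file headers, and were used as deposited. The FPKM values were computed by the authors, and how gene length was set is not given in the sources used here. Count over FPKM, scaled by the library total, differed between the highest and lowest library by a median of 1.04 times over 11096 genes with an FPKM of at least 1 and 10 counts in each library, and by over 1.5 times for 288 of them, so count and FPKM folds can differ for a gene. The authors' mean FPKM per group is the mean of the 3 libraries, with 0.001 in place of 0. The deposited log2 fold change is the log2 ratio of those group means, and was recomputed within rounding. The deposited p-values and FDR come from a test that is not named in the sources used here. The FDR is a Benjamini-Hochberg value over 12468 genes and is 1 for the other 9819. The authors' filtered table holds the 89 genes with a deposited FDR under 0.05 and an absolute deposited log2 fold change over 1, which was checked on the full table. Gene symbols and GO and KEGG terms were taken from the deposited annotation columns.

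The table lists 22287 genes, of which 5716 had no count in any library. Genes were kept by the filterByExpr function of edgeR with its default minimum count of 10 and minimum total of 15, which left 12656 tested genes and 9631 not tested. Library sizes were scaled by TMM. Differences were tested with edgeR 4.0.16 (R 4.3.3), by its robust quasi-likelihood F test with group as the only term, and adjusted over all tested genes by Benjamini-Hochberg at 0.05. Every adjusted p of a single gene is from this test unless another tool is named. Levels are CPM, counts scaled to a common library total with TMM-scaled library sizes, as mean ± SD over 3 libraries, and log2 fold changes are WR against Control with a standard error (SE). The SE was derived from the test, as the absolute log2 fold change over the square root of the F statistic. A fold limit of 2 was applied as an extra criterion. With 3 libraries against 3, an exact two-sided permutation test of a single value cannot give a p below 0.1.

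A set of 29 gene lists was fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists. Called members are counted with the adjustment over all tested genes, and the count adjusted over the list alone is given where it differs. GO and KEGG terms with 10 to 500 members among the tested, annotated genes were tested with a one-sided Fisher exact test for higher and lower genes separately, with the tested genes annotated in the same column as background and adjustment over all 3286 terms of the 4 columns per direction.

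Named genes followed a rule fixed at the same time: 8 Wnt feedback genes in any case (Axin2, Lef1, Nkd1, Rnf43, Znrf3, Lgr5, Sp5 and Notum), the 8 largest rises and 8 largest falls among called genes with a mean of at least 2 CPM and no overlap of the groups, the 4 smallest adjusted p per direction, and the 2 called members with the smallest adjusted p in each list (4 in the Wnt target list and in the list with the most called members). From a list of markers of another cell type with no called member, the member with the highest level was to be named. Some genes that the rule picks are not reported here. Other genes are marked in the text as chosen after their values were seen.

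Depth ranged from 13188229 to 18887119 counts per library. In counts simulated from these libraries, with 200 of 12632 tested genes changed, edgeR recovered 70% of the genes changed 1.25-fold, 88% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 17 false calls. The list and term tests, run on simulated data with 20 lists of which 1 was moved, called that list and no other. Each gene was simulated independently of the others, so this cannot show false calls that come from correlation between genes. In the real libraries the estimated correlation of the DNA replication list was 0.73. The alternatives were DESeq2 size factors, library totals, no filter on low counts, a filter of 50 counts in 3 libraries, the replicate number as a block, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1 and without that filter, and leaving out each library in turn. The list tests with the replicate block and an estimated correlation or fry were added after seeing the data. GC content and length for the test of those trends were medians over the transcripts of each gene in GENCODE M21, read with Biostrings 2.70.1 and matched by gene identifier.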

Results

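Gene expression was measured by bulk RNA sequencing in cultured mouse neural stem cells, which renew themselves and can form neurons and glia. The cells came from the brain (hippocampus and subependymal tissue) of a C57BL/6 embryo at gestation day 12.5. Of the 6 libraries, 3 were from untreated cells (Control) and 3 from cells given Wnt3a and R-spondin 1 at 50 ng/ml each for 24 hours (WR). Wnt3a is a secreted ligand that activates β-catenin signalling, and R-spondin 1 is a secreted protein that strengthens the response to Wnt ligands. Total counts were 14270004, 14667701 and 15628087 in Control replicates 1 to 3 and 18887119, 18628649 and 13188229 in WR replicates 1 to 3. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which can be technical. Replicates differed by more than sampling noise, with a chi-square over its degrees of freedom of 2.02 to 6.07 within groups, and each was counted as its own sample.

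The comparison asks which genes Wnt3a plus R-spondin 1 regulates in neural stem cells. Of the 8 Wnt feedback genes fixed in advance, 5 rose in WR (Axin2, Rnf43, Nkd1, Znrf3 and Lef1), Lgr5 and Notum did not pass, and Sp5 could not be tested. Axin2 (ENSMUSG00000000142), a scaffold of the β-catenin destruction complex that the pathway itself induces, rose 2.98-fold, from 52.0 ± 0.753 CPM (SD, n = 3) to 155 ± 1.27 CPM (SD, n = 3). Its log2 fold change was 1.58 (SE 0.047, edgeR adjusted p = 1.68e-14), and the exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. Rnf43 (ENSMUSG00000034177), a ubiquitin ligase that removes Wnt receptors from the surface, rose 11.9-fold, from 1.71 ± 0.327 to 20.5 ± 1.18 CPM. Nkd1 (ENSMUSG00000031661), an inhibitor of Dishevelled, rose 4.45-fold, from 64.9 ± 1.09 to 289 ± 19.8 CPM, with the smallest adjusted p of all tested genes in edgeR (1.27e-15).

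Znrf3, the paralog of Rnf43, rose by less, with a log2 fold change of 0.46 (SE 0.053). Lef1, a transcription factor that acts with β-catenin, rose by 1.72 (SE 0.29, edgeR adjusted p = 0.000325) from a low level of 0.863 ± 0.202 to 2.90 ± 0.708 CPM. Tnfrsf19, a receptor of the TNF family, rose 3.02-fold to 279 ± 5.56 CPM. Lgr5, a receptor for R-spondins, had 6.47 ± 1.32 CPM in Control and 6.09 ± 0.768 in WR (log2 fold change -0.11, adjusted p = 0.690). Notum, a secreted enzyme that inactivates Wnt ligands, had 1.48 ± 0.156 and 1.16 ± 0.486 CPM (log2 fold change -0.30, adjusted p = 0.543). Sp5 had 0, 1 and 0 counts in Control and 2, 2 and 2 in WR, below the filter of at least 15 counts in total, so it was not tested.

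Of the 30 Wnt target and feedback genes listed, 20 could be tested, of which 7 rose, 3 fell and 10 did not pass. Apcdd1, an inhibitor of Wnt ligands, was the other gene that rose (log2 fold change 1.36, chosen after its values were seen). The 3 that fell, also chosen after their values were seen, are known as drivers of cell growth and of the G1 phase. Myc fell by 0.59 on the log2 scale (SE 0.078), Ccnd2 by 0.92 (SE 0.14) and Ccnd1 by 0.48 (SE 0.11). The list was called higher by camera (adjusted p = 0.00533) and by fry (adjusted p = 0.00165), but not by camera with an estimated correlation (adjusted p = 0.648). That setting called none of the lists, even at an unadjusted p under 0.05, so a lost call there does not set a list apart. With the libraries regrouped so that Control and WR were mixed, camera with the preset correlation still called 1 to 7 lists. A camera call thus does not by itself tie a list to the real groups. With the replicate block, fry did not call the Wnt target list (adjusted p = 0.101). The Ccnd1 call was lost without Control replicate 1 (edgeR adjusted p = 0.0675), Control replicate 2 (0.0766) or WR replicate 2 (0.0796). It was also lost with no filter on low counts (0.0856) or with the replicate block (0.0577).

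**Figure D1:**
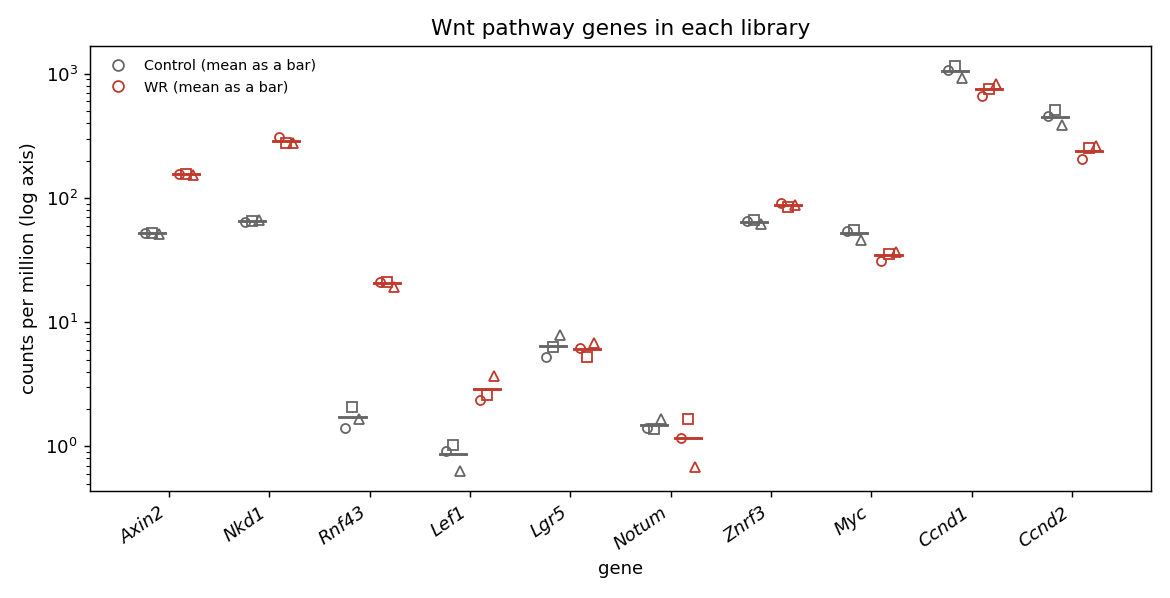
CPM (log axis) of 10 Wnt pathway genes in each of the 3 Control (grey) and 3 WR (red) libraries, with circles, squares and triangles for replicates 1, 2 and 3 and a bar at each group's mean. Axin2, Nkd1, Rnf43, Lef1 and Znrf3 lie higher in each WR library than in any Control library, Myc, Ccnd1 and Ccnd2 lie lower, and the groups overlap for Lgr5 and Notum.

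Over the transcriptome, most called changes were small. Of 12656 tested genes, 2667 passed in edgeR, 1137 higher and 1530 lower in WR, and 113 of them changed at least 2-fold, 70 higher and 43 lower. The median size of a called change was 0.29 on the log2 scale, a 1.22-fold change, and 85.3% of called genes changed by under 1.5-fold. The 3 WR libraries lay apart from the 3 Control libraries in 36.5% of tested genes, where chance gives 10%. Among the 8 largest rises, besides Rnf43, Nkd1, Tnfrsf19 and Axin2 of the Wnt target and feedback list, were the potassium channel Kcnk9 (8.02-fold, from 0.696 ± 0.141 to 5.65 ± 0.339 CPM), the crystallin Crybb1 (3.57-fold), the thyroid hormone activating deiodinase Dio2 (3.42-fold) and the collagen Col22a1 (3.19-fold, a log2 fold change of 1.67). On the authors' FPKM values the change of Col22a1 was far smaller, 0.21 on log2(FPKM + 1) and 0.47 on log2(FPKM + 0.1), and not called by limma (adjusted p = 0.615 and 0.555). Arl4a, a small GTPase, rose 2.89-fold to 103 ± 2.19 CPM and had the next smallest adjusted p after Nkd1, Axin2 and Tnfrsf19 (1.92e-13).

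The 8 largest falls were led by the histone gene Hist1h4b (4.23-fold lower), whose reads may not have been told apart from those of near-identical histone copies. They included Fam155a (3.96-fold lower, from 7.78 ± 0.796 to 2.01 ± 0.585 CPM), Tm4sf1 (3.82-fold lower), Adamtsl3 (3.42-fold lower) and Spp1, which encodes the secreted phosphoprotein osteopontin (2.88-fold lower). Crispld2 was 2.59-fold lower, the serotonin receptor Htr6 2.53-fold lower, and Id1, an inhibitor of bHLH transcription factors induced by BMP signals, 2.54-fold lower (27.3 ± 1.54 to 10.7 ± 0.481 CPM). The smallest adjusted p among lower genes belonged to Olfm2 (1.95e-10, 2.35-fold lower), Fabp7 (2.99e-10), Sorcs1 (1.32e-09, 1.93-fold lower) and Id1 (2.91e-09). Each WR library lay on one side of each Control library for every gene named by the rule that passed, except Adm. The rule required this of the 8 largest rises and 8 largest falls and took the others by their adjusted p, so it is no separate support. Without 1 library, edgeR called 1496 genes (without Control replicate 1), 1671 (without Control replicate 2), 1749 (without WR replicate 1) or 1557 (without WR replicate 2), against 3610 without Control replicate 3. On the authors' FPKM values, limma called 1429 genes on log2(FPKM + 1).

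Genes of DNA replication and of the G1/S transition were lower in WR. Of 26 listed, 22 fell, or 25 when adjusted over the list alone, and the median log2 fold change was -0.39. Cdc6, which loads the replicative helicase, fell 1.72-fold, from 22.0 ± 2.44 to 12.8 ± 0.658 CPM, and Fen1, the flap endonuclease, fell by 0.41 (SE 0.063). Rrm2, a subunit of ribonucleotide reductase, fell by 0.32 (SE 0.056), and Mcm7, a subunit of the replicative helicase, by 0.33 (SE 0.060). The list was called lower by camera (adjusted p = 6.68e-10) and not with an estimated correlation (adjusted p = 0.648), nor by fry (adjusted p = 0.0529). Without Control replicate 1, 14 members fell, against 24 without Control replicate 3.

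The mean log2 CPM of the replication list was 6.39, 6.43 and 6.12 in Control replicates 1 to 3 and 5.88, 5.93 and 5.98 in WR replicates 1 to 3, so that Control replicate 3 lay nearest to WR. The same library lay nearest to WR on principal component 1 of log2 CPM, which held 47.8% of the variance, at -7.50 where the other Control libraries lay at -15.3 and -22.3 and the WR libraries at 14.2 to 15.9. On component 2 it stood apart from all other libraries, at -17.9 where they lay at -1.91 to 8.32. Correlations of log2 CPM over genes were 0.992 to 0.995 within groups and 0.985 to 0.991 between them. Genes of mitosis moved less. Of 24 listed, Ccnb2 (chosen after its values were seen) rose by 0.17, 3 fell and 20 did not pass, with a median of -0.06 and no call by camera (adjusted p = 0.0823). Cdk1, the mitotic kinase, and Aurkb, which corrects chromosome attachment, each fell by 0.19. Mki67 (log2 fold change -0.05) and Top2a (-0.06), proliferation markers chosen after their values were seen, did not pass. The Ccnb2 call was lost in each fit without 1 library (adjusted p from 0.0510 to 0.150), that of Cdk1 without Control replicate 1 (0.0921) or WR replicate 2 (0.0901), and that of Aurkb without Control replicate 1 (0.0554), Control replicate 2 (0.0866) or WR replicate 2 (0.0922). Limma on log2(FPKM + 1) did not call Aurkb (adjusted p = 0.0602). The count of mitosis genes lower was 0 without Control replicate 1 or WR replicate 2 and 1 without Control replicate 2. Without Control replicate 3, 8 mitosis genes fell and camera called the list lower (adjusted p = 0.0253). With all libraries and an estimated correlation, camera did not call it (adjusted p = 0.702).

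**Figure D2:**
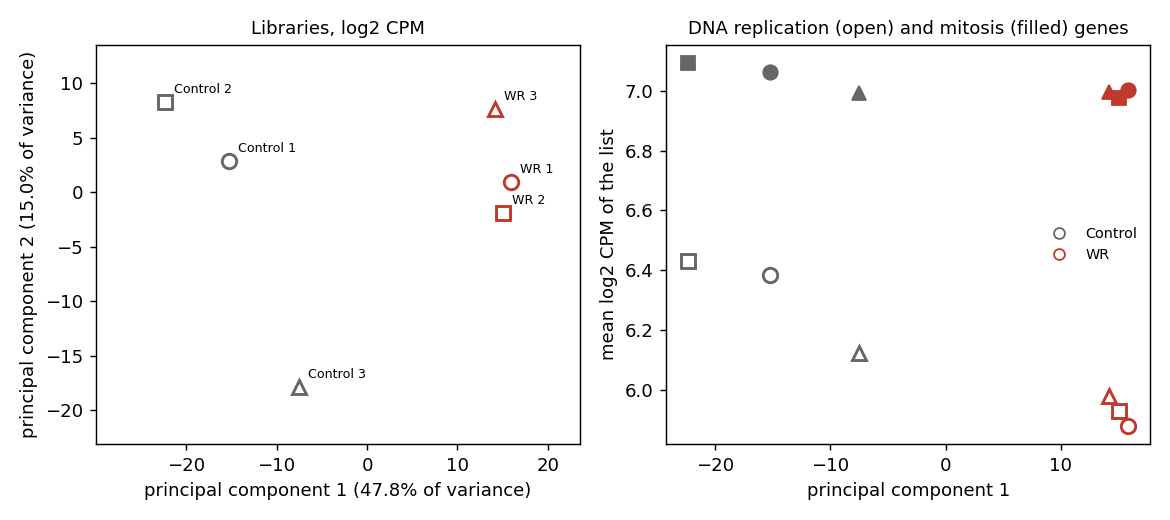
Left, positions of the 3 Control (grey) and 3 WR (red) libraries on principal components 1 and 2 of log2 CPM; right, the mean log2 CPM of the DNA replication list (open symbols) and of the mitosis list (filled symbols) against component 1, with circles, squares and triangles for replicates 1, 2 and 3. The replication mean is 6.12 to 6.43 in Control and 5.88 to 5.98 in WR, with Control replicate 3 the Control library nearest to WR on component 1 and in this mean, but apart from all others on component 2 (-17.9).

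Part of the genes of cholesterol synthesis, FGF and MAPK feedback, matrix and adhesion and apoptosis fell, and camera called these 4 lists lower. None of the 4 was called with an estimated correlation (adjusted p = 0.648 for each). Of 22 cholesterol synthesis genes, 10 fell, or 11 adjusted over the list alone, such as Dhcr7, which makes cholesterol in the last step of one branch (-0.28), and the lanosterol demethylase Cyp51 (-0.25). The mean log2 CPM of this list was 6.98, 6.99 and 6.88 in Control replicates 1 to 3 and 6.79, 6.76 and 6.84 in WR replicates 1 to 3, with Control replicate 3 again nearest to WR. Feedback genes of FGF and MAPK signalling included 9 of 15 that fell and 2 that rose, with the transcription factor Etv4 1.72-fold lower and the receptor kinase inhibitor Spry1 lower by 0.59 on the log2 scale. Of 23 matrix and adhesion genes, 9 fell (12 adjusted over the list alone) and 2 rose, with the laminin-binding integrin Itga6 1.40-fold lower and the matrix glycoprotein Tnc 2.17-fold lower (806 ± 91.7 to 371 ± 19.1 CPM). Of 24 apoptosis regulators, 5 fell, among them cytochrome c (Cycs, -0.44) and the survival factor Bcl2 (-0.48), which act in opposite directions.

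In camera the adjusted p was 0.000474 for cholesterol synthesis, 0.0427 for FGF and MAPK feedback, 0.0375 for matrix and adhesion and 0.0401 for apoptosis. Fry did not call FGF and MAPK feedback (adjusted p = 0.140) or cholesterol synthesis (0.0574), and with genes of more than 1 list left out camera called neither FGF and MAPK feedback nor matrix and adhesion (adjusted p = 0.0739 for each). The cholesterol count was 4 without Control replicate 2 or WR replicate 2, 5 without Control replicate 1 and 6 without WR replicate 1 or 3, the FGF and MAPK count of falls was 5 without Control replicate 1, the apoptosis count was 3 without WR replicate 2, and the matrix and adhesion count of rises was 1 without Control replicate 1, WR replicate 2 or WR replicate 3. The camera call was lost for FGF and MAPK feedback without Control replicate 2 (adjusted p = 0.0508), Control replicate 3 (0.0677) or WR replicate 1 (0.108), for matrix and adhesion without Control replicate 3 (0.127) or WR replicate 1 (0.0866), and for apoptosis without WR replicate 1 (0.129).

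Dorsal neural tube and neural crest genes and mitochondrially encoded genes were called higher by camera, with small changes. With an estimated correlation neither list was called (adjusted p = 0.648 and 0.688). Of 6 tested dorsal and crest genes of 20 listed, 4 rose: the zinc finger factors Zic2 (0.43, SE 0.079), Zic5 (0.44, SE 0.096) and Zic1 (0.13), and the crest and oligodendrocyte factor Sox10 (0.72), with Zic1 and Sox10 chosen after their values were seen. Of 13 mitochondrial genes, 3 rose, or 4 adjusted over the list alone, namely mt-Nd5 (0.18), mt-Nd4 (0.15) and mt-Nd4l (0.16, chosen after its values were seen), which encode subunits of respiratory complex I. Mitochondrial genes took 2.92%, 2.77% and 3.06% of counts in Control replicates 1 to 3 and 3.03%, 3.27% and 3.19% in WR replicates 1 to 3. The adjusted p was 0.0427 for the dorsal list and 0.0323 for the mitochondrial list in camera. Fry did not call the mitochondrial list (adjusted p = 0.182), and with genes of more than 1 list left out camera did not call the dorsal list (adjusted p = 0.0739). Each of these calls was lost in 3 of the 6 fits without 1 library: the dorsal list without Control replicate 1 (adjusted p = 0.0862), WR replicate 1 (0.0880) or WR replicate 3 (0.0513), and the mitochondrial list without Control replicate 2 (0.0972), WR replicate 2 (0.0682) or WR replicate 3 (0.0678). Zic1 was lost in each such fit and Sox10 without Control replicate 1, Control replicate 2, WR replicate 1 or WR replicate 2 (adjusted p of at least 0.0796), mt-Nd4 without Control replicate 1, WR replicate 2 or WR replicate 3, mt-Nd5 without Control replicate 1 or WR replicate 2, and mt-Nd4l without Control replicate 2 or any WR replicate. The dorsal count was 2 without Control replicate 1, Control replicate 2, WR replicate 1 or WR replicate 2, and the mitochondrial count 1 without Control replicate 1 or WR replicate 3, 0 without WR replicate 2, 5 without WR replicate 1 and 6 without Control replicate 3. With no filter on low counts the dorsal list had a camera adjusted p of 0.612. Limma on log2(FPKM + 1) did not call Zic1 (adjusted p = 0.0665), Sox10 (0.0713) or mt-Nd4l (0.0742).

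Stem cell and lineage markers moved in both directions, and none of their lists was called. Of 23 neural stem cell and radial glia markers, 5 rose and 7 fell. The radial glial lipid-binding protein Fabp7 fell 1.70-fold (1704 ± 63.3 to 999.8 ± 34.3 CPM) and Tnc 2.17-fold. Sox2 (log2 fold change 0.07) and Pax6 (0.11), stem cell factors chosen after their values were seen, did not pass. Of 15 neurogenic genes, 7 rose and 2 fell, with the Notch-modifying enzyme Mfng 1.67-fold higher. Of 18 neuronal markers, 2 rose (3 adjusted over the list alone) and 5 fell, among them Rtn1 (-0.38) and the growth cone protein Gap43 (-0.54). Astrocyte markers gave 8 higher and 2 lower of 17 (9 and 3 adjusted over the list alone), with a median log2 fold change of 0.18. The 2 with the smallest adjusted p, the bicarbonate transporter Slc4a4 (-0.53) and Acsbg1 (-0.41), were those that fell, against the direction of most of the list. Of 13 oligodendrocyte lineage markers, 5 rose and 4 fell. The myelin gene Mbp rose 1.67-fold, and the lineage factor Olig2 fell by 0.16.

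Camera gave these lists adjusted p of 0.953 (stem cell), 0.302 (neurogenic), 0.659 (neuronal), 0.0632 (astrocyte) and 0.406 (oligodendrocyte). Fry came near to calling the stem cell list lower (adjusted p = 0.0529) and gave the others adjusted p of at least 0.197. The stem cell list had a median of 0.06 but a mean of -0.05 and a test direction of lower, and the neuronal list a median of -0.03, a mean of 0.02 and a test direction of lower. Without Control replicate 3, camera called the astrocyte list higher (adjusted p = 0.0253). With all libraries and an estimated correlation, camera did not call the astrocyte list (adjusted p = 0.702). Counts that moved by over 1.5 times were 4 and 5 astrocyte genes higher without WR replicates 1 and 2, 3 stem cell genes higher without Control replicate 1 or WR replicate 2, 3 neuronal genes lower without Control replicate 1 or WR replicate 2, 2 and 1 oligodendrocyte genes lower without Control replicate 2 and WR replicate 2, and 1 neurogenic gene lower without Control replicate 2, WR replicate 1 or WR replicate 2. The Olig2 call was lost without WR replicate 2 (adjusted p = 0.0552), and Sox2 passed without Control replicate 3 (adjusted p = 0.0197).

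Markers of cells other than the neural lineage were few and mostly low. Of 18 microglia markers, 3 could be tested and 0 passed in edgeR, DESeq2 or limma-voom (0 at an unadjusted p under 0.05). Of 9 endothelial markers tested, 3 fell and 1 rose: the sialomucin Emcn fell 1.77-fold (31.9 ± 3.08 to 18.1 ± 0.766 CPM), and the tight junction scaffold Tjp1, which many cell types express, rose by 0.24. Of 6 pericyte and fibroblast markers tested, Pdgfra, which oligodendrocyte precursors also express, rose by 0.56 and Myl9 fell by 0.43. Camera gave adjusted p of 0.134 (endothelial) and 0.898 (pericyte), and the 3 microglia genes were too few for it. The Myl9 call was lost without any library other than Control replicate 3 (adjusted p of at least 0.0600) and in DESeq2 (0.0798), and that of Pdgfra on log2(FPKM + 1) (0.0564).

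In the other signalling lists genes moved in both directions, and camera called none of these lists, though fry called 2 of them. Of 42 Wnt receptors, ligands and pathway components, 8 rose (9 adjusted over the list alone) and 10 fell, with Wls, which carries Wnt proteins to the surface, 1.43-fold higher and the ligand Wnt7a 1.48-fold lower. The Notch list had 4 higher (5 adjusted over the list alone) and 3 lower of 20, with Lfng lower (-0.31). BMP and TGF-beta response genes had 1 higher and 3 lower of 13 (2 and 4 adjusted over the list alone), led by Id1 and Id2 (1.43-fold lower). Hedgehog genes had 2 higher and 3 lower of 12: the ligand Shh rose 2.06-fold (7.05 ± 1.46 to 14.5 ± 0.123 CPM), Gli1, a Hedgehog target, rose 2.46-fold, the co-receptor Gas1 fell by 0.36, and the receptor and target Ptch1 did not pass (0.05), with Gli1 and Ptch1 chosen after their values were seen. Ventral neural tube genes had 1 higher, Shh, and 3 lower of 7. Among 15 immediate early genes 2 rose and 2 fell, with Fos 1.52-fold higher and Dusp1 1.27-fold lower. Growth factors had 2 higher (3 adjusted over the list alone) and 2 lower of 18, with pleiotrophin (Ptn, 2123 ± 102 to 2647 ± 51.5 CPM) and Igf1 (1.70-fold) higher.

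Camera adjusted p was 0.953 for Wnt components, 0.344 for Notch, 0.302 for BMP, 0.842 for Hedgehog, 0.262 for ventral genes, 0.393 for immediate early genes and 0.825 for growth factors. The Hedgehog list had a mean of 0.10 but a median of -0.05 and a test direction of lower, and the Wnt component list a median and mean of -0.01 and a test direction of higher. By fry, which asks whether a list moves one way on balance and compares it with no other genes, the BMP list (adjusted p = 0.0278) and the ventral list (0.00165) were called lower, and with an estimated correlation camera called neither (adjusted p = 0.648 for each). Without 1 library, Wnt components had 4 or 5 genes higher (without Control replicate 1, WR replicate 1 or WR replicate 2) and 6 lower (without WR replicate 1 or 2), and the ventral list 1 gene lower (without Control replicate 1 or 2, or WR replicate 1) or 0 (without WR replicate 2). The BMP list had 0 genes higher without Control replicate 1, Control replicate 2, WR replicate 1 or WR replicate 2, and the immediate early list 1 lower without Control replicate 1, WR replicate 1 or WR replicate 2.

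The lists of integrated stress, p53, glycolysis and hypoxia, interferon and ribosomal protein genes were called neither by camera nor by fry. Integrated stress and unfolded protein response genes came nearest, with 10 lower (11 adjusted over the list alone) and 2 higher of 22 and a camera adjusted p of 0.0581, where the chaperone calreticulin (Calr) fell by 0.37 and the cystine transporter Slc7a11 rose 2.32-fold. Without Control replicate 3 this list was called lower (adjusted p = 0.0418), and with library totals, no filter on low counts or a stricter one it was called too (adjusted p = 0.0438, 0.0312 and 0.0325), but not with an estimated correlation (adjusted p = 0.655). Of 16 p53 targets 2 rose (3 adjusted over the list alone) and 6 fell, with the cell cycle inhibitor Cdkn1a (-0.30) and Aen (-0.29) lower (camera adjusted p = 0.264). Of 24 glycolysis and hypoxia genes 2 rose and 2 fell, with Adm (0.38) and P4ha2 (0.59) higher. The list had a median of -0.04, a mean of 0.02 and a test direction of lower (camera adjusted p = 0.825). Of 12 interferon and inflammatory genes 2 rose (3 adjusted over the list alone) and 2 fell, with Vcam1 1.72-fold higher and Cxcl10 2.74-fold lower. Camera gave the interferon list an adjusted p of 0.344. Of 34 cytosolic ribosomal protein genes 0 passed in edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05. The list's median was 0.01 (camera adjusted p = 0.579).

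The Cxcl10 call, at 11, 12 and 16 counts in Control replicates 1 to 3 and 6, 4 and 6 in WR replicates 1 to 3, was lost without any library other than WR replicate 3 (adjusted p from 0.0509 to 0.111). Adm was lost without any library other than Control replicate 3 and WR replicate 1 (0.0544 to 0.104), and P4ha2 without Control replicate 1 (0.0637) or WR replicate 2 (0.128). Limma on log2(FPKM + 1) called neither Adm (adjusted p = 0.0540) nor P4ha2 (0.0761). Of the p53 targets, 1 was higher without Control replicate 1, Control replicate 2, WR replicate 1 or WR replicate 2 and 4 without Control replicate 3, and 3 were lower without WR replicate 2. Glycolysis and hypoxia genes higher numbered 0 without Control replicate 1 or WR replicate 2 and 1 without Control replicate 2 or WR replicate 3, and those lower 1 without Control replicate 1 and 0 without Control replicate 2, WR replicate 1 or WR replicate 2. Interferon genes higher numbered 1 without Control replicate 1, WR replicate 2 or WR replicate 3, and those lower 0 without Control replicate 1, Control replicate 2 or WR replicate 2 and 1 without any other library.

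**Figure D3:**
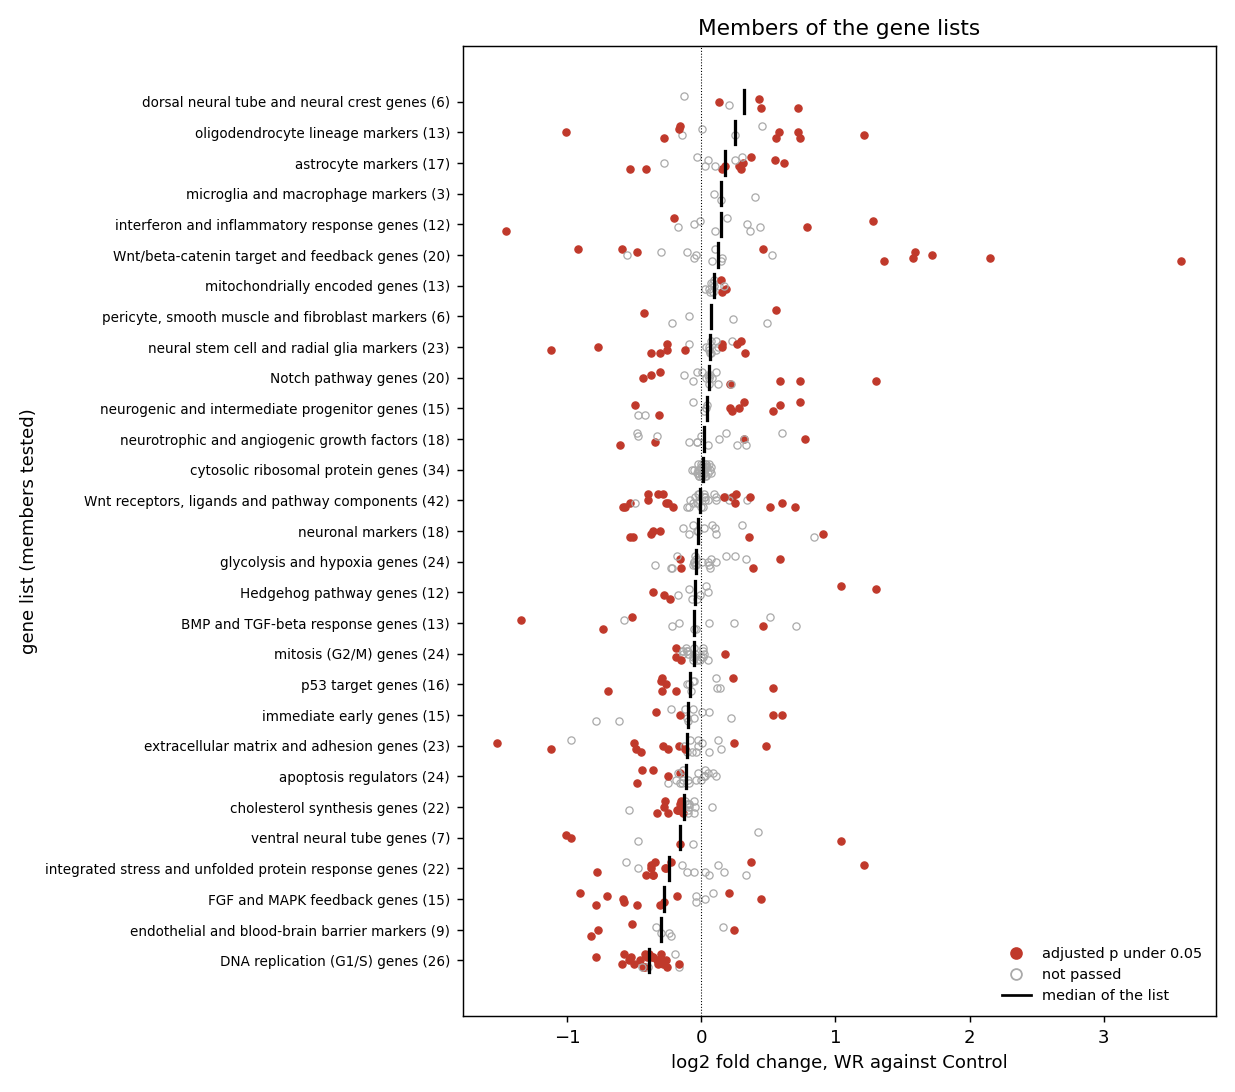
Log2 fold change, WR against Control, of each tested member of the 29 gene lists, with filled red points for adjusted p under 0.05 in edgeR, open grey points for members that did not pass and a black bar at the list's median. The DNA replication list has the lowest median, -0.39, with 22 of 26 members lower, and Rnf43, at 3.58, is the farthest point.

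Annotation terms, tested on the same gene calls, gave the same main group as the fixed lists. In Fisher's exact test, 141 of 3286 terms were enriched among lower genes and 4 among higher genes. The lower count was 80 without WR replicate 2, and the higher count 2 without Control replicate 2 or WR replicate 1, 7 without Control replicate 3 and 0 without WR replicate 3 (230 at an unadjusted p under 0.05 with all libraries). With genes changed at least 2-fold the test called 0 terms (174 at an unadjusted p under 0.05). The GO process DNA replication had 53 of its 117 tested genes lower (adjusted p = 1.86e-15), and the KEGG pathway of that name 26 of 35 (adjusted p = 2.72e-11). Fisher's exact test counts genes as independent, so its p-values, for all terms, do not allow for genes that move together. The fixed DNA replication list had an estimated inter-gene correlation of 0.73. With estimated correlations camera called neither that list (adjusted p = 0.648) nor any other. Terms of the cytoskeleton and of adhesion were also enriched among lower genes, with 25 of 69 stress fiber genes (adjusted p = 0.000119) and 47 of 156 genes of the KEGG focal adhesion pathway (adjusted p = 0.00068). The actin-binding protein Zyx (-0.52) and the integrin Itgb5 (-0.77) were among them, chosen after their values were seen. Among higher genes, cerebellum development had 15 of 42 (adjusted p = 0.00613), with Gbx2, a hindbrain patterning factor, up by 0.87 and the kinase Pak1 by 0.36, both chosen after their values were seen, and axon had 57 of 347 (adjusted p = 0.00785). Of the called terms, 35, all lower, were called in every fit without 1 library, among them DNA replication in both sources, stress fiber and focal adhesion. Cerebellum development was called in 1 of the 6 such fits (adjusted p up to 0.381) and axon in 4 (up to 0.109). Neural terms were enriched among lower genes too in Fisher's exact test. Among them were myelin sheath (adjusted p = 4.74e-08), positive regulation of neuron projection development (0.000425) and postsynapse (0.0149), each called in all 6 such fits.

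The authors' deposited table lists 1971 genes with an FDR under 0.05, 836 higher and 1135 lower, of which 1950 were also called here. Their filtered table holds 89 genes, 54 higher and 35 lower, and 87 of them were called here in the same direction, 53 higher and 34 lower. The other 2 were predicted genes with low counts. Gm26920 was not tested here, and Gm27029 had a log2 fold change of -1.32 and an edgeR adjusted p of 0.0524, which passed without Control replicate 3 (adjusted p = 0.00199) or WR replicate 2 (0.0218). Of the genes called here, 11 have an FDR of 1 in the authors' deposited table.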

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

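The list tests with the replicate block combined with an estimated correlation or with fry were chosen after seeing the data, and the other alternatives were planned. Axin2 stayed higher and past the threshold under every alternative, with a log2 fold change of 1.57 to 1.59 when single libraries were left out. Of 1149 values of 73 named genes under alternatives, 1098 stayed on the same side of the threshold, 51 no longer passed and 0 reversed. These 51 came from 15 genes, 9 of which lost the call in a fit without 1 library. Of 538 values of 34 genes chosen after their values were seen, 491 stayed, 42 no longer passed, 5 newly passed and 0 reversed. Of 445 values of gene lists, 44 no longer passed, 9 newly passed, 0 reversed and the others stayed. The cause was not tested for any change below unless it is given.

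Without 1 library, called genes numbered 1496 (without Control replicate 1) to 3610 (without Control replicate 3), with 639 to 1666 higher and 857 to 1944 lower. Those changed at least 2-fold numbered 88 to 164, with 52 to 105 higher and 31 to 59 lower. Called lists numbered 4 (without WR replicate 1) to 9. Called terms numbered 85 (without WR replicate 2) to 164, with 0 (without WR replicate 3) to 7 higher and 80 to 164 lower, and between 81 and 89 called genes were in the authors' filtered table. Limma on log2(FPKM + 1) called 1429 genes (654 higher, 775 lower), 28 of them changed at least 2-fold (15 higher, 13 lower). On log2(FPKM + 0.1) it called 1430 (654 higher, 776 lower) and 53 (32 higher, 21 lower), and without the filter 843 (398 higher, 445 lower) and 28 (15 higher, 13 lower). A pseudocount of 1 by its construction shrinks the fold of genes with low FPKM. The stricter filter left 54 genes changed at least 2-fold (35 higher, 19 lower), since it tests fewer genes of low level. DESeq2 called 2087 genes (2068 shared with edgeR) and limma-voom 2640 (2601 shared).

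Camera with an estimated correlation called 0 lists (0 at an unadjusted p under 0.05), where camera with the preset value called 8. For the dorsal list the estimated correlation was -0.07, yet the unadjusted camera p rose from 0.0112 to 0.0601. A call lost in that setting is thus not by itself a sign of correlation between genes. Fry called 6, 4 of them also called by camera, and did not call DNA replication (adjusted p = 0.0529), cholesterol synthesis (0.0574), FGF and MAPK feedback (0.140) or the mitochondrial list (0.182), but called the BMP (0.0278) and ventral (0.00165) lists. With members of more than 1 list left out 5 were called, and FGF and MAPK feedback, the dorsal list and matrix and adhesion were not (0.0739 each). With all annotated genes of the file as background 506 terms were called (41 higher, 465 lower), since that background includes genes too low to test. With genes changed at least 2-fold, Fisher's exact test called 0 terms, 0 higher and 0 lower (174 at an unadjusted p under 0.05). On the 500 most variable genes the mean correlation was 0.906 within and 0.844 between groups and component 1 held 44.9% of the variance, and on log2(FPKM + 1) these were 0.996, 0.992 and 52.9%.

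The libraries share replicate numbers, but the deviations of same-numbered libraries from their group means had correlations of 0.0687, 0.00836 and -0.0639, and 2 of the 6 libraries correlated best with their own number, so the numbers were not taken to pair the libraries. With the replicate block, edgeR called 2422 genes (1025 higher, 1397 lower, 2361 of them shared), and camera called 9 lists, the integrated stress list among them (adjusted p = 0.0487). Ccnd1 (adjusted p = 0.0577), Zic1 (0.0756) and Ccnb2 (0.0591) did not pass, and Gm27029 did (0.00347). With the replicate block, camera with an estimated correlation called 0 lists (0 at an unadjusted p under 0.05) and fry 0 (6 at an unadjusted p under 0.05).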

Other observations

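Annotation terms outside the fixed lists gave further groups, and the genes named here were chosen after their values were seen. Among higher genes, breakdown of valine, leucine and isoleucine had 14 of 44 members (adjusted p = 0.0156), with the aldehyde dehydrogenase Aldh2 up by 0.54 and the isovaleryl-CoA dehydrogenase Ivd by 0.41 on the log2 scale. Lysosome had 47 of 290 (adjusted p = 0.0374), with the endolysosomal channel Tpcn1 up by 0.47 and Itm2c by 0.35. Each of these 2 terms was called in 1 of the 6 fits without 1 library, with an adjusted p up to 0.168 and 0.833.

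Among lower genes were groups of protein synthesis, folding and transport. Protein import into the nucleus had 25 of 75 members lower (adjusted p = 0.000389, up to 0.0797 without 1 library), with the pore protein Nup85 lower by 0.34. Unfolded protein binding had 23 of 85 (adjusted p = 0.00985, up to 0.0969), with the chaperones Hspa8 lower by 0.34 and Hspa5 by 0.36. Aminoacyl-tRNA ligases, which charge transfer RNAs, had 14 of 41 (adjusted p = 0.0126, called in 1 of the 6 fits without 1 library and up to 0.932), with Iars lower by 0.35 and Gars by 0.26. Chondroitin sulfate synthesis had 7 of 12 (adjusted p = 0.0105, at most 0.0446 without 1 library), with the sulfotransferases Chst7 lower by 0.80 and Chst11 by 0.54.

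The 6 libraries can be split into 3 and 3 in 10 ways, so 10 splits cannot give a share under 0.05. The real split, the 1 split as large as itself in each count, gave 2667 called genes where the highest other gave 0 in edgeR (118 to 875 at an unadjusted p under 0.05, against 4213), 113 against 0 changed at least 2-fold, 8 against 7 lists and 145 against 0 terms. Camera called 1 to 7 lists in each other split, though no gene was called there. Its calls thus do not by themselves tie a list to the real groups. Each other split puts Control and WR libraries in both groups. Any difference between Control and WR then widens the spread within groups and lowers the count of called genes, so these counts of 0 do not show what noise alone gives.

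The tests of the 3 patterns below were all chosen only after the results were seen, so each explanation is a hypothesis. Lower DNA replication genes may come from a trend with GC content and gene length, but with that trend subtracted the list's median log2 fold change was -0.38, against -0.39 before. Fewer cycling cells of every phase could lower the mitosis list too, and its median was -0.0571. A growth state of the cultures apart from the ligands could also separate the groups. An exact two-sided permutation test of the list's mean level per library gave p = 0.1, but 3 libraries against 3 cannot give less, so it decides nothing, and an effect of the ligands and any other difference between the cultures coincide in this design.

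Control replicate 3 lay nearer to the WR libraries than the other Control libraries did, by a share of 0.334 of the distance on component 1. If WR RNA were mixed in, the 7 called-higher members of the Wnt target and feedback list (Tnfrsf19 and Apcdd1 included) would shift by about that share, but on a scale of 0 at the mean of Control replicates 1 and 2 and 1 at the WR mean they had a median shift of -0.00408 (SD 0.0988). DNA replication genes had a median shift of 0.641 (SD 0.117), within the spread of all genes called lower (median 0.393, SD 0.362). That spread is of single genes, so it cannot show whether the median of a list is unusual. The level of the DNA replication genes in this library had also been seen before, so a growth state of Control replicate 3 nearer to that of WR stays open.

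Lower Myc, Ccnd1 and Ccnd2 in WR may reflect the scaling of the libraries. Under the other scalings the highest log2 fold change of the 3 genes was -0.47, but these moved the median of all genes by at most 0.0135 and could not have turned a sign, so they decide nothing. A growth state apart from the ligands could lower them as well. In Control replicate 3 their median shift toward WR was 0.417, close to that of all genes called lower (0.393), so this does not single them out, and neither this explanation nor an effect of the ligands is set apart by it.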
